A study of Homo sapiens with 93 samples.

How the data were processed

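Whole-genome expression was measured in 32 breast cancer cell lines with 93 Affymetrix arrays of 1 colour. Per the labels, total RNA came from untreated cultures and biotin-labelled cRNA was hybridised. Each array was assigned to its line by its own label, with the replicate number given there, which left 29 lines with 3 arrays and 3 lines with 2. The labels name no treatment, no batch and no hybridisation day.

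The values are the deposited table of the series, 1 log2 value per probe set and array, which the authors made with GCRMA in Partek, per the submitters' processing notes. Software versions and the settings of that step are not given in the sources used here. GCRMA subtracts a background predicted from probe sequence, normalises the arrays to each other and summarises the probes of a set on the log2 scale. Probe sets with no signal are therefore pressed together near a floor of about 2, where replicates differ very little. Differences against that floor have very small standard errors and p-values, and their folds depend on the background step. The values ran from 0.79 to 15.32, with array medians of 4.07 to 4.43, and were used as deposited. Scanner files were not used here.

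The table held 22277 probe sets, of which 62 were controls. Through the platform's annotation 19070 probe sets had 1 gene, 1043 several and 2164 were not listed there. Only probe sets with 1 gene were kept, and 19058 of these matched the gene numbers of a current RefSeq table (assembly GRCh38.p14), from which symbols were updated. That table was also used for the order of genes along chromosomes, without coordinates. In all, 31 probe sets of sex-linked marker genes were left out. The probe set with the highest mean over all arrays stood for each gene, which gave 11939 genes, 4304 of them with more than 1 probe set. The 7100 probe sets not chosen correlated with the chosen probe set of their gene over the lines with a median r of 0.78, and the 3267 of them with a mean above the table's median with 0.92.

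Signal rather than depth sets the precision of arrays, and their number limits it. RNA quality was checked by control probe sets. The difference between 3' and 5' probe sets of ACTB had a median of 1.29, from 1.00 in HCC-1954 to 2.05 in HCC-38, with a replicate SD of 0.10, and that of GAPDH ran from -0.29 to 0.06. No pair of arrays held identical values (0 pairs), and 0 columns belonged to no listed sample.

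The tests, the gene lists and the rule for named genes were fixed before the data were examined. A linear model with 1 coefficient per line was fitted to all 93 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 61 residual degrees of freedom before moderation). Genes that differed between lines were found with the moderated F test at a Benjamini-Hochberg adjusted p under 0.05, and counted again with at least 4-fold between the highest and lowest line mean. Each line was contrasted with the equally weighted mean of the other 31 line means, and a gene was called at an adjusted p under 0.05 within the line and at least 2-fold. Gene lists were tested with cameraPR on the moderated t statistics of each line, with an inter-gene correlation preset at 0.01 and adjustment over all 1120 pairs of list and line. That test was repeated with the correlation estimated per list.

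The fixed lists, 35 with 400 of 469 genes measured, covered the BCL-2 family (anti-apoptotic, effector and BH3-only), known regulators of MCL1, its neighbours at 1q21, caspases and IAPs, and epithelial, mesenchymal and hormone programmes. They also covered amplicons, tumour suppressors, proliferation, p53 targets, interferon and MHC genes, cancer-testis antigens, metabolic and stress pathways, and markers of haematopoietic, fibroblast, endothelial, adipocyte, neural and cornified cells. Only the fibroblast and mesenchymal lists shared more than 1 measured gene.

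Relations with MCL1 were computed over the 32 line means in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, as Pearson's r and Spearman's rho, each with a two-sided permutation p from 100000 resamples (smallest possible 1e-05). They were repeated without the 2 lines farthest from the median of MCL1 and within arrays of each replicate number (29 lines for number 3). Lines counted as separate clusters where the largest gap between sorted line means exceeded 30% of the range with at least 3 lines on either side. Line means of all other genes were regressed on MCL1 with limma. Principal components were taken of the line means, centred and not scaled. Figures were drawn with matplotlib 3.10.9.

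The text names every measured BCL-2 family member, the 20 genes with the largest SD of line means among those past the F test, and for each line the called gene with the largest positive difference. It also names, for each list, up to 3 members that differed most in its higher and its lower call with the smallest p. Further named are the 5 genes with the largest positive and the 5 with the largest negative t statistic against MCL1, the 1q21 neighbours past the threshold, and 10 genes at each end of the first component. Any other gene named was chosen after its values were seen.

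The calculations were tested on simulated data with 200 changed genes among 11939. Of genes shifted in HS-578T, 0.0% of those shifted by 0.5 on the log2 scale and 100.0% of those shifted by 1.5 and by 3 were called at the 2-fold limit, with 11 unchanged genes past the adjusted p. The F test found 77.0% of changed genes and 0.10% of the others, and the regression on MCL1 found 84.0% of genes made to follow it, with 3 others. The shifted list had the smallest p, with 1 other pair past the threshold, and 20 of 20 relations simulated with r = 0.8 and 0 of 20 with r = 0 passed. Genes of the simulated arrays were drawn independently of each other. The simulation therefore does not show how the list test fares with correlated genes.

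Alternatives were quantile normalization, centring each array on its median, the mean of all probe sets of a gene, leaving out probe sets with IDs ending in _x_at or _s_at (designed to match several transcripts or genes), and leaving out 2974 dim genes, whose mean was under 4.27 in every line. Others were the replicate number as a block, an intensity trend and robust prior, line medians and leaving out arrays. Leaving out HCC-1599 was added after seeing the data.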

Results

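Steady-state mRNA was measured in 32 established breast cancer cell lines grown without treatment, on 93 single-colour oligonucleotide arrays. Of the lines, 29 had 3 arrays each, and HCC-1395, HCC-1599 and MDA-MB-468 had 2 each. The series' design text calls the arrays of a line biological replicates, and the error is within-line replicate spread. After collapsing probe sets to genes, 11939 genes were measured. Array medians lay between 4.07 and 4.43 on the log2 scale and upper quartiles between 8.52 and 8.71. The lowest correlation between arrays of one line was 0.9943, above the highest between arrays of different lines, 0.9600, and 0 arrays lay closer to another line than to their own. As the only contrast in the labels is the cell line, the comparisons below ask which genes and gene groups set the lines apart, beginning with MCL1, the gene the series is about. The number of arrays limits the precision of every value.

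MCL1, which encodes an anti-apoptotic protein that holds pro-apoptotic members of the BCL-2 family in check, varied 9.48-fold between lines. It was highest in HCC-1599, at 13.79 ± 0.08 (SD, n = 2), followed by HCC-1187 at 12.64 and HCC-2218 at 12.42. The lowest line mean was 10.54 ± 0.10 (SD, n = 3) in HCC-1419, with HCC-1937 next at 10.59, and the median of the lines was 11.80. The range of 3.25 compared with a replicate SD of 0.09 (limma moderated F test, adjusted p = 7.91e-48 over all genes and 5.21e-48 adjusted over the list alone). The SD of its line means, 0.71, was close to the median over all genes, 0.717. MCL1 thus varied between lines about as much as a typical gene. Against the mean of the other 31 lines, MCL1 was called higher in 2 lines and lower in 4. The other 4 MCL1 probe sets correlated with the chosen probe set across lines with r of 0.76, 0.89, 0.82 and 0.95.

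**Figure D1:**
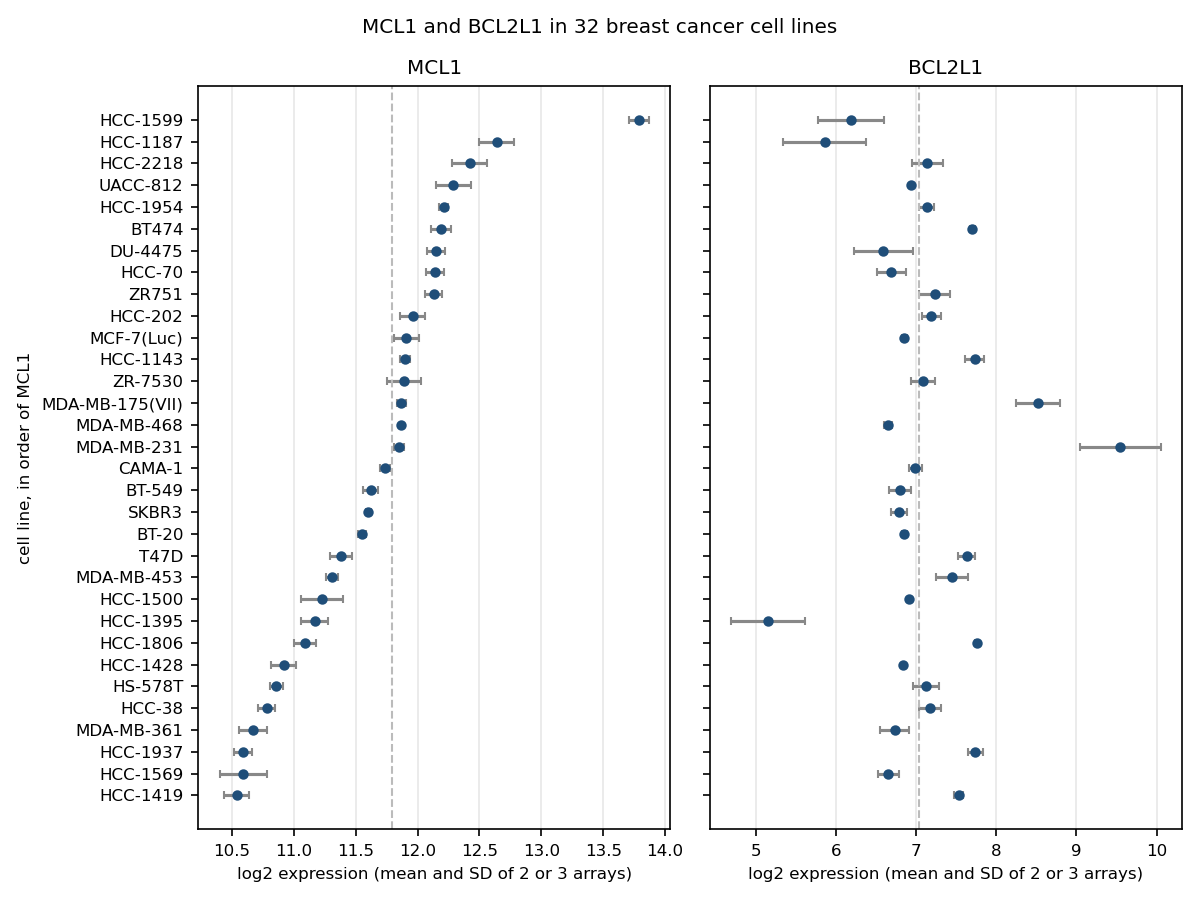
Mean log2 expression of MCL1 (left) and BCL2L1 (right) in each line, ordered by MCL1, with bars for the SD of 2 or 3 arrays and a dashed line at the median of the lines. MCL1 ran from 10.54 in HCC-1419 to 13.79 in HCC-1599, while BCL2L1 was highest in MDA-MB-231 (9.55) and lowest in HCC-1395 (5.15), with no order along MCL1.

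The other anti-apoptotic members were distributed differently over the lines. BCL2, the founding member of the family, reached 11.62 ± 0.17 (SD, n = 3) in HCC-1500, 9.68 in ZR751 and 8.66 in DU-4475, whereas the median line mean was 3.01 and the lowest 2.68 in HCC-202, a 490-fold range. BCL2L1, which encodes BCL-XL, ranged 21.1-fold, from 9.55 ± 0.50 (SD, n = 3) in MDA-MB-231 to 5.15 ± 0.46 (SD, n = 2) in HCC-1395. BCL2A1, a member best known from blood cells, was high in DU-4475 alone, at 12.50 ± 0.21 (SD, n = 3), with the next line, HCC-1599, at 3.04. BCL2L2, which encodes BCL-w, varied 4.54-fold, from 10.12 in HCC-1419 to 7.94 in HCC-1599, the lines with the lowest and the highest MCL1. Across all lines BCL2L2 and MCL1 showed no relation beyond chance (Spearman's rho = -0.12, permutation p = 0.502). Pearson's r was -0.25 (permutation p = 0.168), and 0.03 without HCC-1599 and HCC-1419. BCL2L10 stayed near the lower end of the scale in all lines, with a range of 0.06.

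Among the pro-apoptotic members, PMAIP1, which encodes the MCL1-binding protein NOXA, had the widest range, 1533-fold between MDA-MB-231 at 12.90 ± 0.07 (SD, n = 3) and HCC-1419 at 2.32 ± 0.03 (SD, n = 3). BIK ranged from 10.22 in HCC-1143 to 2.57 in HS-578T, and BID from 10.79 in HCC-38 to 6.74 in HCC-1428. HRK was called higher in 4 lines, BT-20 (6.47), HCC-70 (6.12), HCC-1599 (5.56) and HCC-1937 (4.91), over a median of 2.41. BAD (range 2.48), BCL2L11, which encodes BIM (2.30), and the effector BAK1 (3.06) varied less. BAX, the other main effector, spanned 4.43, from 9.33 in HCC-1500 to 4.90 in HCC-1599, but its replicate SD of 0.68 was the largest of the family (adjusted p = 7.44e-09). Of the 17 fixed members, 15 were measured (BBC3 and BMF were not). In all, 14 passed limma's moderated F test over all genes, 14 also when adjusted over the list alone, and 13 of these spanned at least 4-fold. Of all 11939 genes tested, 97.1% passed that test, so passing it does not set the family apart. BOK passed with a range of 0.14 (adjusted p = 6.16e-06), and BCL2L10 did not pass (adjusted p = 0.118 over all genes, 0.116 adjusted over the list alone). BCL2L10 did pass with an intensity trend and robust prior (adjusted p = 0.016). It also passed with arrays centred on the median (range 0.36, adjusted p = 1.26e-23). As deposited, its line means lay only between 1.75 and 1.81, while array medians ran from 4.07 to 4.43. Centring passes the differences between array medians on to such a gene, so that pass says nothing on BCL2L10 itself. For BCL2 the other probe sets correlated with the chosen one by only 0.53, 0.33 and 0.50, and for HRK by -0.18 and 0.77; the others of BCL2 and HRK lay near the lower end of the scale.

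**Figure D2:**
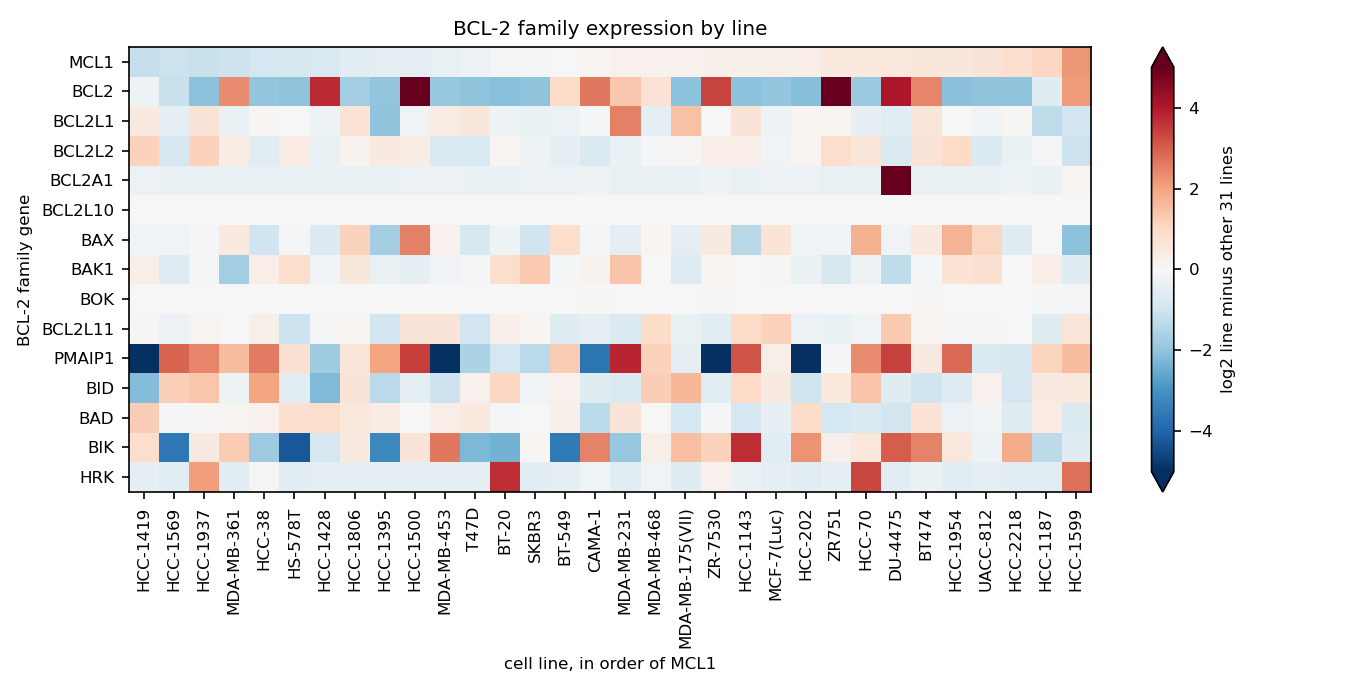
Difference of each line from the mean of the other 31 lines for the 15 measured BCL-2 family genes (rows), as log2 colour from blue (lower) to red (higher) with the scale limited to ±5, and lines (columns) in order of MCL1. BCL2A1 stands out in DU-4475 and PMAIP1 is low in HCC-1419 and HCC-202, with line means of 2.32 and 2.51.

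Whether a line with more MCL1 had less of another family member was asked across the 32 line means. MCL1 and BCL2L1 showed no relation beyond chance, with Pearson's r = -0.14 (permutation p = 0.454, adjusted p = 0.738) and Spearman's rho = -0.14 (permutation p = 0.433, adjusted p = 0.977). Without HCC-1599 and HCC-1419, the lines farthest from the median of MCL1, r was 0.01 (permutation p = 0.944), and within replicates 1, 2 and 3 it was -0.16, -0.20 and 0.05. Replicate 3 covers only 29 lines, without HCC-1395, HCC-1599 and MDA-MB-468, so its values are not from the same set of lines. Arrays of one line correlated by at least 0.9943, so similar values within replicates were to be foreseen. With the mean of all probe sets per gene the sign turned, to r = 0.10 (permutation p = 0.587). Of the 13 relations tested in the family, 0 passed the Benjamini-Hochberg adjustment of the permutation test by rho and 1 had an unadjusted p under 0.05. This was BAD, which encodes a BH3-only protein that binds BCL2 and BCL-XL, with rho = -0.47 (p = 0.00729, adjusted p = 0.0948) and r = -0.48 (p = 0.00583, adjusted p = 0.0758). For BAD, r was -0.37 without HCC-1599 and HCC-1419 (permutation p = 0.0446) and -0.41, -0.48 and -0.44 within replicates 1, 2 and 3. When probe sets with IDs ending in _x_at or _s_at were left out, the BAD relation passed, at rho = -0.52 (adjusted p = 0.029). That setting kept the BAD probe set and replaced the MCL1 probe set, and fewer family members entered the adjustment. HRK fell into separate clusters of lines, so no pooled value was computed; in the larger cluster of 28 lines, r was -0.04 (permutation p = 0.84) and rho -0.11 (permutation p = 0.572), and the other cluster was too small to test.

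Of 20 measured genes that lie near MCL1 on 1q21, 11 correlated with it across the lines past the threshold by rho, all with a positive sign; with the other MCL1 probe sets the number was between 1 and 11. The closest was GOLPH3L, which encodes a Golgi phosphoprotein, with rho = 0.69 (permutation p = 4e-05, adjusted p = 0.0007) and r = 0.66 (p = 5e-05, adjusted p = 0.000867). For GOLPH3L, r was 0.67 without HCC-1599 and HCC-1419 and 0.66, 0.65 and 0.66 within replicates 1, 2 and 3 (29 lines in replicate 3). The others, by rho, were RPRD2 at 0.67, the cathepsin gene CTSK at 0.59, ARNT, the dimer partner of hypoxia-inducible factors, at 0.57, the histone methyltransferase gene SETDB1 at 0.57, PRUNE1 at 0.56, CDC42SE1 at 0.55, the splicing factor genes SF3B4 at 0.52 and PRPF3 at 0.50, VPS45 at 0.52 and CTSS at 0.41. Without the 2 extreme lines, 10 of the 11 kept an unadjusted permutation p under 0.05 by r. CTSS was weakest, with adjusted p = 0.0385 by rho, r = 0.34 (permutation p = 0.0615) and r = 0.35 without the 2 lines (permutation p = 0.053). Its adjusted p was 0.0616 without the arrays numbered 1, 0.115 without those numbered 3, 0.0707 without HCC-1599 and 0.0925 with quantile normalization. PRPF3 had adjusted p = 0.0713 with the mean of all probe sets. ENSA (rho = 0.36) and CERS2 (rho = 0.37), both with adjusted p = 0.0659, and MLLT11 (rho = -0.32, adjusted p = 0.101) were among those that did not pass. With the mean of all probe sets ENSA (rho = 0.53, adjusted p = 0.0125) and CERS2 (rho = 0.41, adjusted p = 0.0355) did, and CERS2 also with quantile normalization (adjusted p = 0.0472). The count fell to 1, GOLPH3L, when probe sets with IDs ending in _x_at or _s_at were left out, a setting that also replaces the MCL1 probe set.

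**Figure D3:**
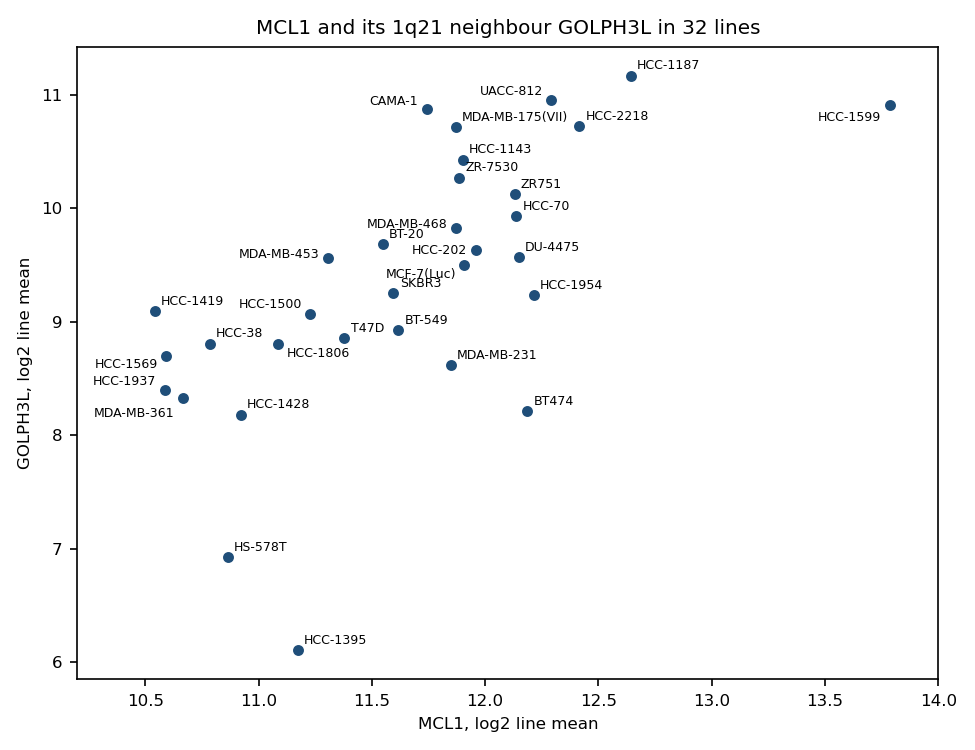
Line means of MCL1 (x axis) and its neighbour GOLPH3L (y axis), both log2, with a point for each of the 32 lines. Spearman's rho was 0.69, and r was 0.67 without HCC-1599 (right) and HCC-1419 (left).

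In a regression of all other 11938 genes on the MCL1 line mean, VPS72, a chromatin remodelling gene also on 1q21, was the only gene past the threshold. Its slope was 0.86 (SE 0.15, limma adjusted p = 0.0392), and 941 genes had an unadjusted p under 0.05. The next by t statistic on the positive side were PROM1, which encodes the stem cell surface marker CD133, with a slope of 3.82 (adjusted p = 0.0682), GOLPH3L at 1.06, the RNA polymerase III subunit gene POLR3C at 0.74 and the receptor gene NOTCH1 at 1.22, the last 3 with adjusted p = 0.074. On the negative side, DOHH, which encodes an enzyme that modifies a translation factor, had a slope of -0.56 (adjusted p = 0.0682). OAZ1 (-0.34), the histone chaperone gene CHAF1A (-0.60), B9D1 (-1.15) and SAMM50 (-0.83) followed at adjusted p = 0.074. VPS72 did not pass without the arrays numbered 1 (slope 0.86, adjusted p = 0.0549) or without HCC-1599 (slope 0.98, adjusted p = 0.0827). Its slope fell, and did not pass, with the mean of all probe sets (0.63, adjusted p = 0.196) and without _x_at and _s_at probe sets (0.52, adjusted p = 0.92). Without the arrays numbered 3, PROM1 and DOHH passed as well, each with adjusted p = 0.0368, PROM1 also passed without dim genes (adjusted p = 0.0325), and without _x_at and _s_at probe sets the DOHH slope was 0.00.

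Over the whole array, TFF1 and TFF3, trefoil peptides of mucous epithelia, had the largest SD of line means and spanned 3795-fold (14.52 in HCC-2218 to 2.63 in HCC-70) and 4617-fold (14.14 in MDA-MB-175(VII) to 1.97 in HCC-1806), with replicate SDs of 0.32 and 0.28. The mammary secretory genes SCGB2A2 and SCGB1D2 were highest in ZR-7530, at 15.15 and 14.19, and the disulphide isomerase family gene AGR2 in T47D, at 14.46. Caveolin-1 (CAV1) and vimentin (VIM) peaked in HS-578T, at 14.23 and 14.82, and the membrane-cytoskeleton linker gene MSN and the methyltransferase gene NNMT in BT-549, at 12.79 and 13.56. TGFBI, a secreted matrix protein gene, ran from 14.38 in HCC-1395 to 1.99 in T47D.

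Among the same genes, LDHB, a lactate dehydrogenase subunit gene, was at 14.38 in HCC-1937 and 2.29 in HCC-1500, and GPX1, which encodes a peroxide-reducing selenoenzyme, at 13.22 in HCC-70 and 1.54 in HCC-1187. AKR1C2, a steroid-metabolising reductase gene, was highest in HCC-1395 (13.90), and IGFBP3 and RARRES1 in HCC-70 (14.85 and 14.24). The kallikrein gene KLK5 was highest in HCC-1937 (13.99), BASP1 in HCC-1143 (13.17), S100P in ZR-7530 (13.88) and the cancer-testis gene MAGEA6 in HCC-1428 (13.48). S100A8, which encodes a calcium-binding alarmin, had the widest range of these, 12.73, with a replicate SD of 0.64. These were the 20 genes with the largest SD of line means, the adjusted p nearest the threshold being 2.1e-46 for S100A8. The moderated F test passed 11589 genes, 97.1% of those tested, and 8315 of them spanned at least 4-fold. The median replicate SD was 0.135 and the median SD of line means 0.717. Folds against values near 2 are folds against the lower end of the scale.

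Each line also had genes that set it apart from the panel. REG1A, a secreted lectin-like gene of pancreas and gut, was at 14.76 ± 0.08 (SD, n = 3) in HCC-1569 and no higher than 2.11 in any other line. DKK4, an inhibitor and target of WNT signalling, was at 14.46 ± 0.06 (SD, n = 3) in DU-4475 and at most 1.94 elsewhere. ELN, which encodes elastin, was confined in the same way to HCC-1187 (12.52 ± 0.43, SD, n = 3, others at most 1.98), and the gastric mucin gene MUC5AC to HCC-2218 (11.12 ± 0.03, SD, n = 3, others at most 2.32). ALB, which encodes serum albumin, was 10.64 above the other lines in HCC-1500 (SE 0.02), and the collagenase gene MMP1 was 11.32 above them in HCC-1806 (SE 0.03). All of these passed limma's contrast of the line with the mean of the other 31 lines (adjusted p = 9.7e-125 for REG1A, 1.17e-127 for DKK4, 2.83e-89 for ELN, 2.87e-103 for MUC5AC, 5.77e-106 for ALB and 9.75e-105 for MMP1). These p-values use a spread pooled over all lines, so they do not measure the spread within the named line. For ELN the SE of the difference was 0.05, although its own arrays in HCC-1187 had an SD of 0.43.

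Other leading genes were shared by a few lines. TCN1, which encodes a vitamin B12 binder, was 11.10 above the other lines in BT474 and 10.43 in MDA-MB-361. GABRP, a GABA receptor subunit gene, led in HCC-1599 (10.59) and HCC-1143 (9.76), the transcription factor gene TFAP2B in MDA-MB-453 (9.27) and HCC-202 (8.44), and SCGB2A2 in UACC-812 (9.70) and ZR751 (9.03), with SCGB2A1 in ZR-7530 (10.14). Collagen genes led in HS-578T (COL3A1, 11.64) and HCC-1395 (COL1A2, 9.62), and the BMP antagonist gene CHRDL1 in BT-549 (9.89). Squamous genes led in HCC-70 (SERPINB4, 2047-fold), MDA-MB-468 (S100A7, 10.22) and HCC-1937 (KLK10, 9.76). Steroid-related genes led in T47D (SERPINA6, corticosteroid-binding globulin, 11.23) and BT-20 (HSD17B1, which makes estradiol, 9.49), and lipid carriers in CAMA-1 (FABP7, 10.72) and MDA-MB-175(VII) (FABP4, 10.29). The remainder were G0S2 in MDA-MB-231 (9.43), the carboxylesterase gene CES1 in HCC-1954 (9.24), the chemokine gene CXCL14 in HCC-1428 (9.18), SERHL2 in SKBR3 (8.72), CCN5 in MCF-7(Luc) (8.55), PNMT, an adrenaline-synthesis gene beside ERBB2, in HCC-1419 (8.30) and transferrin (TF) in HCC-38 (8.24). TF was at 11.66 in HCC-38 but at 14.19 in HCC-1569, and COL1A2 at 12.79 in HCC-1395 but at 14.31 in HS-578T. The TF call in HCC-38 ended without _x_at and _s_at probe sets, where its difference was 0.07 (adjusted p = 0.652).

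Summed over the lines there were 81805 calls, 41450 higher and 40355 lower, with a median of 2470 genes per line. DU-4475 had the most, 3740 (1677 higher and 2063 lower), then HCC-1187 with 3275 and HS-578T with 3247, and ZR751 the fewest, 2123. The fold limit set this count, since 81806 pairs of gene and line differed by at least 2-fold whatever their p. In MDA-MB-453, 47% of calls were higher as deposited and 58.4% with each array centred on its median.

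Where 1 line is singled out for a list below, it is the line with the smallest cameraPR p in that direction. That line need not have the largest mean difference. Where members lie near the lower end of the scale, a lower call can reflect a few other lines with high values. Of 299 calls over all lists and lines, 231 held with an estimated correlation. In 100 groupings of the arrays, the real one included, the highest other count was 227. Random groupings could thus pass many pairs as well, so single list calls are less certain than their adjusted p. Luminal epithelium genes, such as keratins of glandular cells and the transcription factor genes GATA3 and FOXA1, were higher in 15 lines and lower in 10, of which HCC-1187 was lost (adjusted p = 0.123 with an estimated correlation). In ZR751 all 16 members were called higher (adjusted p = 1.09e-18), with TFF3 up by 4.88, AGR2 by 4.65 and the carbonic anhydrase gene CA12 by 4.04. In HCC-1395, 15 were lower and 1 higher (adjusted p = 9.27e-41), with keratin 19 (KRT19) at 2.07 ± 0.01 (SD, n = 2) against 11.81 in the other lines, and the adhesion genes EPCAM and CDH1 at differences of -8.79 and -8.55. Genes of tight and adherens junctions were lower in 5 lines and higher in 15, of which the higher calls in HCC-1143, MCF-7(Luc), HCC-1500 and HCC-1428 were lost (adjusted p = 0.0513, 0.0907, 0.0959 and 0.111 with an estimated correlation). All 13 members were lower in BT-549 (adjusted p = 7.49e-38), among them CDH1 by -8.55, the splicing regulator gene ESRP1 by -7.86 and RAB25 by -7.41. The higher call with the smallest p was HCC-202 (adjusted p = 7.67e-07), with CLDN3 up by 5.66, CDH1 by 2.96 and CLDN4 by 1.98.

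Mesenchymal genes were higher in 6 lines and lower in 17. In HS-578T all 18 were higher (adjusted p = 1.53e-61), led by COL3A1, COL6A3 (11.20) and SPARC (10.44), and in T47D 14 were lower (adjusted p = 1.98e-11), with TGFBI at -5.95, MSN at -5.03 and CAV1 at -4.43. Fibroblast markers, which share 3 genes with that list, were higher in HS-578T (11 of 12, adjusted p = 2.02e-128, LUM by 10.06 and COL1A2 by 11.19), BT-549 (5 of 12, median 0.36, mean 2.92) and HCC-1395 (5 of 12, median 0.03, mean 1.85). They were lower in 8 lines, with the smallest p in ZR751 (adjusted p = 0.00627, FBN1 by -1.55, COL3A1 by -1.15, COL1A2 by -1.14). These 3 genes lay near the lower end of the scale in ZR751, at 2.80, 2.76 and 2.36. Their means over the other lines were 4.35, 3.91 and 3.51, with HS-578T at 13.06, 15.15 and 14.31. All 8 of the lower calls were lost (adjusted p = 0.0775 in ZR751 to 0.212 in BT-20 with an estimated correlation, and 0.276 in ZR751 without _x_at and _s_at probe sets). Basal epithelium genes were higher in 9 lines and lower in 15, of which MDA-MB-175(VII) and MDA-MB-361 were lost (adjusted p = 0.0599 and 0.0677 with an estimated correlation). In HCC-1937 all 12 were higher (adjusted p = 8.74e-17), with the keratins KRT16 up by 6.13 and KRT14 by 5.52 and TRIM29 by 5.56, and in CAMA-1 11 were lower (adjusted p = 1.38e-08), with the growth factor receptor gene EGFR at -5.79, KRT15 at -3.01 and TRIM29 at -2.74.

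Estrogen response genes were higher in 10 lines and lower in 11, of which the BT-549 call (adjusted p = 0.0357) ended without its replicate 2 (0.0516). In T47D all 13 were higher (adjusted p = 2.7e-25), with the chemokine gene CXCL12 up by 7.75, the progesterone receptor gene PGR by 6.83 and SERPINA1 by 5.92. In HCC-38, 10 were lower (adjusted p = 1.36e-05), with TFF1 at -4.95, the estrogen receptor gene ESR1 at -4.69 and NAT1 at -3.98. Androgen and apocrine genes were higher in 7 lines, most in UACC-812 (5 of 9, adjusted p = 2.54e-06, SCGB2A2 by 9.70, HPGD by 6.04 and PIP by 3.30). The same list was lower in 4 lines, with the smallest p in HCC-38 (7 of 9, mean -2.27, adjusted p = 2.19e-06, ALCAM by -7.02, SCGB2A2 by -3.33 and PIP by -3.03) and the lowest mean in BT-20 (-2.39, also 7 of 9). HCC-1569 and MCF-7(Luc) were lost (adjusted p = 0.0513 and 0.0775 with an estimated correlation). In ZR751 the median of that list was -0.18 while its mean was 1.41 and its test upward. SCGB2A2 lay near the lower end of the scale in HCC-38, at 2.51, with the lowest line mean at 2.485 in HCC-1143.

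**Figure D4:**
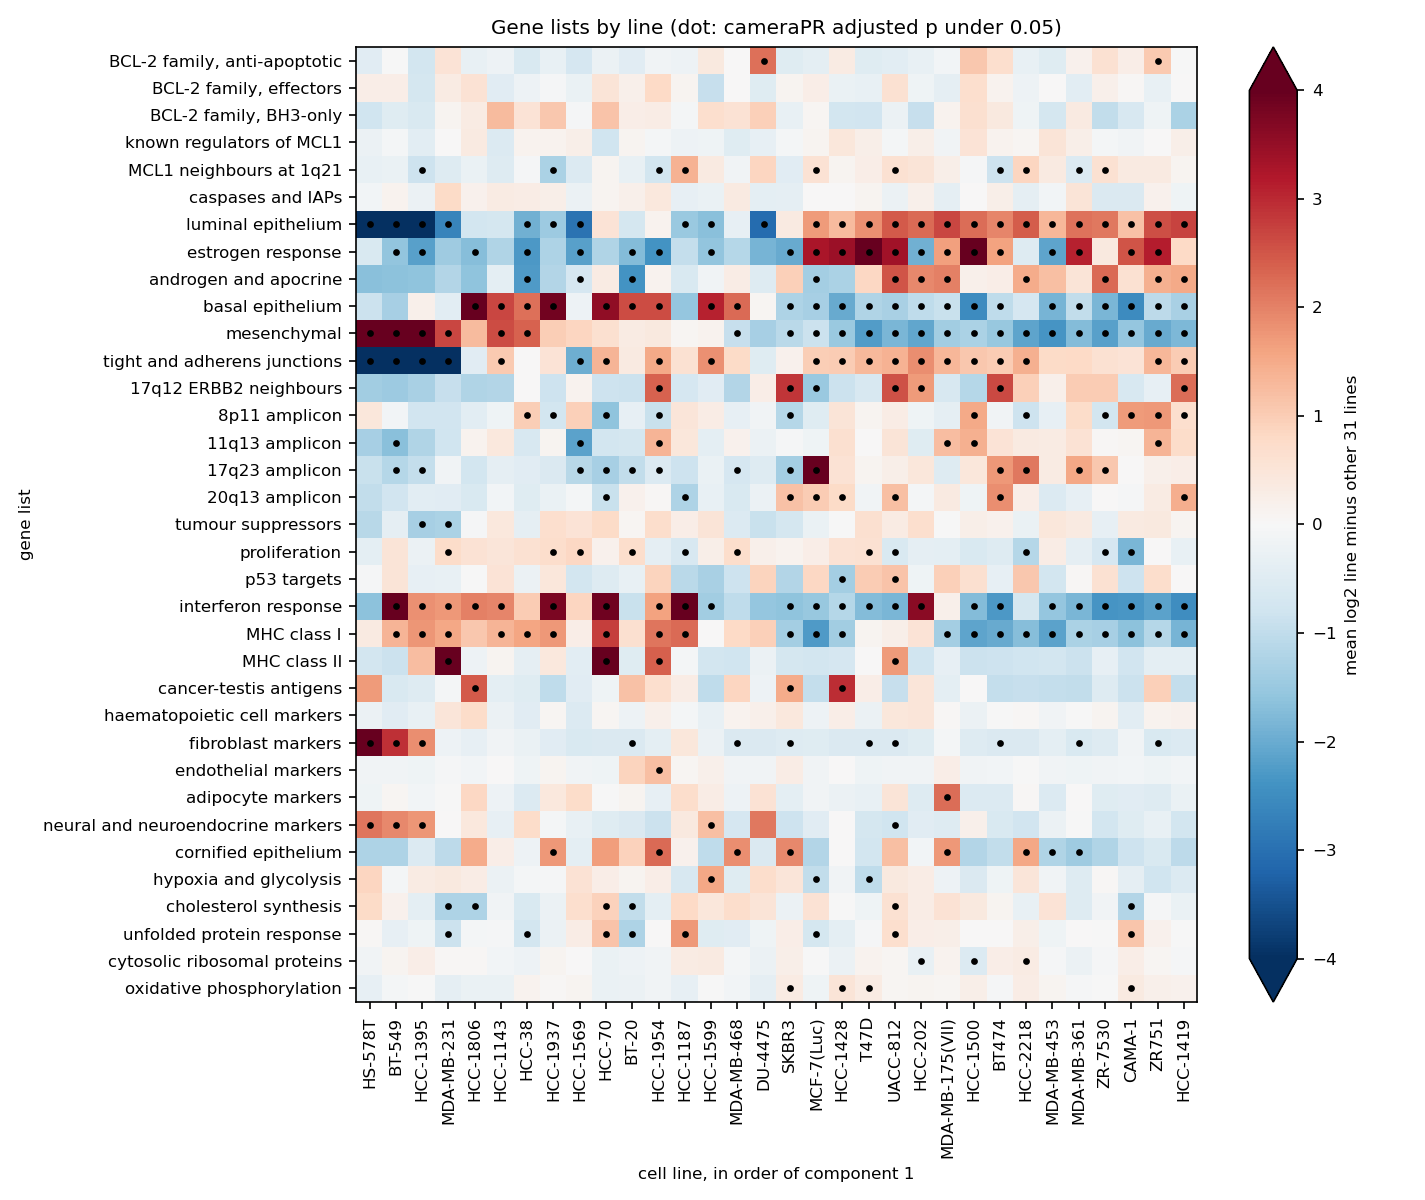
Mean log2 difference of each of the 35 gene lists (rows) in each line (columns, ordered by the first component) from the other 31 lines, blue for lower and red for higher with the scale limited to ±4, and a dot where cameraPR's adjusted p was under 0.05. Of 1120 pairs, 155 were higher and 144 lower past the threshold, and the luminal list was higher in 15 lines and lower in 10.

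Sets of neighbouring genes at known breast cancer amplicons were higher in particular lines. The 17q12 genes around ERBB2, the receptor gene targeted by trastuzumab, were higher in SKBR3 (8 of 11, adjusted p = 2.59e-08), BT474, UACC-812, HCC-1419 (5 of 11, with 2 lower; median 0.37, mean 2.24), HCC-1954 (5 of 11; median 0.31, mean 2.37) and HCC-202 (7 of 11, with 1 lower), the last with adjusted p = 0.0552 with an estimated correlation. In SKBR3, ERBB2 was at 13.52 ± 0.11 (SD, n = 3) against 9.59 elsewhere, with GSDMB up by 7.94 and the kinase gene CDK12 by 4.19. The same list was lower in MCF-7(Luc) (adjusted p = 0.00884, PGAP3 by -3.44, GRB7 by -2.70 and STARD3 by -2.64), a call lost with adjusted p = 0.128 with an estimated correlation and adjusted p = 0.0799 without _x_at and _s_at probe sets. The 17q23 genes were higher in 5 lines, above all MCF-7(Luc) (8 of 9, adjusted p = 1.35e-39, BCAS3 by 8.05, TBX2 by 5.56 and the helicase gene BRIP1 by 4.99). Lower values were called in 8, most in SKBR3 (adjusted p = 2.54e-06, TUBD1 by -2.30, APPBP2 by -2.25, BRIP1 by -1.77). Of these, MDA-MB-468, HCC-1954, HCC-1569 and HCC-1395 were lost (adjusted p = 0.0976, 0.102, 0.108 and 0.125 with an estimated correlation).

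At 8p11, genes were higher in 5 lines and lower in 6, with 11 of 12 higher in ZR751 (adjusted p = 4.44e-12, the receptor gene FGFR1 by 2.87, RAB11FIP1 by 2.67, NSD3 by 2.32) and 8 lower in HCC-70 (adjusted p = 7.04e-08, BRF2 by -2.89, LSM1 by -2.74, PLPBP by -2.30). The 11q13 genes were higher in 4 lines, with the smallest p in ZR751 (6 of 8, mean 1.37, adjusted p = 4.57e-05, the chloride channel gene ANO1 by 4.21, SHANK2 by 1.70, CTTN by 1.38) and the largest mean in HCC-1500 (1.42). Of the 2 lines in which they were lower, HCC-1569 had the smaller p (adjusted p = 0.00164). There the cyclin D1 gene CCND1 was at -8.72, SHANK2 at -5.27 and ANO1 at -1.17. The 20q13 genes were higher in 6 lines, most in BT474 (8 of 11, adjusted p = 1.24e-11, BCAS1 by 5.65, PFDN4 by 2.41, RAE1 by 2.33). In 2 lines they were lower, HCC-1187 first (adjusted p = 0.00148, the mitotic kinase gene AURKA by -2.73, PFDN4 by -2.10, RAE1 by -2.08), a call that ended without _x_at and _s_at probe sets (adjusted p = 0.17), and HCC-70, lost with adjusted p = 0.0576 with an estimated correlation. The MCL1 neighbours at 1q21 were higher in 5 lines, most in HCC-1187 (14 of 20, adjusted p = 0.000151, PLEKHO1 by 6.20, SETDB1 by 3.20, RPRD2 by 2.82). Another 5 had lower values, most of all HCC-1937 (13 of 20, adjusted p = 2.19e-06, ANXA9 by -3.33, SETDB1 by -2.37, CERS2 by -2.23), and 6 of the 10 calls held, with MCF-7(Luc), MDA-MB-361, ZR-7530 and HCC-1395 lost (adjusted p = 0.083 to 0.0988 with an estimated correlation).

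Immune-response genes differed widely between lines in the absence of any treatment. Interferon response genes were higher in 10 lines and lower in 14. Of these calls 15 held, while HCC-1806, HCC-1954, MDA-MB-231 and HCC-1395 on the higher side and HCC-1500, MCF-7(Luc), MDA-MB-453, HCC-1428 and HCC-1599 on the lower side were lost (adjusted p = 0.0513 to 0.238 with an estimated correlation). All 15 were higher in BT-549 (adjusted p = 6.73e-18, IFI44L by 6.98, the antiviral GTPase gene MX1 by 6.63, IFIT1 by 6.61) and 11 were lower in ZR751 (adjusted p = 1.11e-07, IFITM1 by -5.23, ISG15 by -4.03, IFIT1 by -3.43). MHC class I genes, which present intracellular peptides, were higher in 9 lines and lower in 13, of which MDA-MB-231, HCC-1428, ZR-7530 and BT-549 were lost (adjusted p = 0.0524, 0.0534, 0.0561 and 0.156 with an estimated correlation). They were highest in HCC-70 (9 of 10, adjusted p = 6.16e-08, the immunoproteasome genes PSMB9 by 5.49 and PSMB8 by 4.40, HLA-B by 3.20). The lowest were in MCF-7(Luc) (adjusted p = 3.04e-08, PSMB8 by -5.01, PSMB9 by -4.09, HLA-B by -3.71), a call with adjusted p = 0.107 without _x_at and _s_at probe sets. MHC class II genes were higher in 4 lines, HCC-70 (8 of 10, adjusted p = 8.09e-15, HLA-DRA by 8.31, CD74 by 7.60, HLA-DPB1 by 5.68), MDA-MB-231, HCC-1954 and UACC-812. Cancer-testis antigens, normally restricted to germ cells, were higher in HCC-1428 (8 of 13, adjusted p = 3.05e-12, MAGEA12 by 8.41, MAGEA6 by 7.82, MAGEA1 by 7.45), HCC-1806 and SKBR3, and in the latter pair the list's median was -0.02 with a positive mean.

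Adipocyte markers were higher in MDA-MB-175(VII) (3 of 9, with 1 lower and a median of 0.06 against a mean of 2.22; adjusted p = 1.95e-11), with the fatty acid carriers FABP4 up by 10.29 and CD36 by 6.44 and the adipogenic regulator gene PPARG by 4.29. Endothelial markers were higher in HCC-1954 (2 of 9, adjusted p = 0.0046, PECAM1 by 5.82 and CDH5 by 5.55, median of the list -0.02 against a mean of 1.21). Neural and neuroendocrine markers were higher in 4 lines, most in HS-578T (5 of 12, adjusted p = 3.07e-08, the secretory granule genes SCG5 by 8.39 and SCG2 by 7.58 and the neurofilament gene NEFL by 7.44). They were lower in UACC-812 (adjusted p = 0.0494, ENO2 by -3.02, UCHL1 by -2.56, SCG2 by -1.31), but not past the threshold with adjusted p = 0.182 with an estimated correlation, 0.0533 with an intensity trend and robust prior, 0.107 without the arrays numbered 1, 0.0506 to 0.0566 without any 1 of the line's own arrays, 0.0845 with the mean of all probe sets and 0.134 without _x_at and _s_at probe sets. Medians of the neural list were negative beside positive means and tests in HS-578T (-0.00), HCC-1599 (-0.08) and HCC-1395 (-0.02). Haematopoietic cell markers were called in 0 lines by cameraPR, with an unadjusted p under 0.05 in 1 line (lowest adjusted p = 0.11).

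Cornified epithelium genes were higher in 6 lines, most in HCC-1954 (4 of 12, adjusted p = 0.000721, S100A7 by 8.90, S100A8 by 7.96, S100A9 by 7.14), where the median was -0.03 and the mean 2.26, as in MDA-MB-468 with -0.01 and 1.87. At the other end were 2 lines, most of all MDA-MB-361 (adjusted p = 0.00719, S100A8 by -5.14, S100A9 by -3.59, KRT10 by -2.16), where the call ended without _x_at and _s_at probe sets (adjusted p = 0.214). The other, MDA-MB-453, was lost (adjusted p = 0.0523 with an estimated correlation).

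Proliferation genes were lowest in CAMA-1 (16 of 18 lower, adjusted p = 7.08e-16), with the cell cycle transcription factor gene FOXM1 at -3.46, CDC20 at -3.12 and MCM4 at -3.00. The higher call with the smallest p, MDA-MB-468 (7 of 18, mean 0.70, adjusted p = 0.00186, CDC20 by 1.87, TYMS by 1.61, CENPF by 1.24), was lost (adjusted p = 0.148 with an estimated correlation). The mean was larger in HCC-1569 (0.84), MDA-MB-231 (0.73, 10 of 18), BT-20 (0.71) and HCC-1937 (0.71). In all, 2 of the list's 11 calls held in that way, CAMA-1 and HCC-2218 (adjusted p = 0.0402 with an estimated correlation). Unfolded protein response genes were higher in 4 lines and lower in 4, with the smallest p in each direction in CAMA-1 (8 of 14 higher, adjusted p = 2.95e-05, the glutathione-degrading enzyme gene CHAC1 by 4.13, ASNS by 2.78, TRIB3 by 2.14) and BT-20 (8 lower, adjusted p = 1.93e-06, ASNS by -3.37, XBP1 by -2.70, TRIB3 by -2.05). HCC-38, MDA-MB-231, UACC-812 and MCF-7(Luc) were lost (adjusted p = 0.0604, 0.0994, 0.1 and 0.116 with an estimated correlation). HCC-1187 had a larger mean difference than CAMA-1, 1.73 against 1.10. Cholesterol synthesis genes were higher in 2 lines, first UACC-812 (adjusted p = 0.00751, FDPS by 1.89, LSS by 1.28, SC5D by 1.12), and HCC-70, lost with adjusted p = 0.0828 with an estimated correlation. Of the 4 lines with lower values, MDA-MB-231 came first (adjusted p = 0.000757, SQLE by -3.75, HMGCS1 by -2.84, DHCR7 by -2.18).

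Hypoxia and glycolysis genes were higher in HCC-1599 (10 of 15, adjusted p = 0.00349, NDRG1 by 4.44, ADM by 4.04, PDK1 by 2.52), with adjusted p = 0.174 with an estimated correlation. They were lower in T47D (5 of 15, with 2 higher; median -0.33, mean -1.01; adjusted p = 0.00848, NDRG1 by -5.68, EGLN3 by -3.41, the glucose transporter gene SLC2A1 by -2.77), with adjusted p = 0.226 with an estimated correlation and 0.427 without _x_at and _s_at probe sets, and in MCF-7(Luc), with 0.347 with an estimated correlation. Oxidative phosphorylation genes were higher in 4 lines, first HCC-1428 (2 of 17, adjusted p = 0.00959, NDUFS3 by 1.47, NDUFS7 by 1.15), where COX4I1 lay 0.87 above the others; all 4 calls were lost (adjusted p = 0.244 in HCC-1428 to 0.336 in T47D with an estimated correlation). Cytosolic ribosomal protein genes were lower in HCC-1500 (adjusted p = 0.000959, RPL19 by -1.21, RPS12 by -1.14, with RPL11 at -0.88) and HCC-202, and higher in HCC-2218 (adjusted p = 0.0494) with 0 of 10 members at 2-fold and RPL3, RPS12 and RPL10A at 0.59, 0.57 and 0.55. None of the calls held (adjusted p = 0.0972 with an estimated correlation for HCC-1500, 0.321 for HCC-202 and 0.338 for HCC-2218). HCC-1500 and HCC-2218 were also lost without _x_at and _s_at probe sets (0.161 and 0.883), HCC-202 without its replicate 2 (0.0592), and HCC-2218 with quantile normalization (0.173), with arrays centred (0.0617), without dim genes (0.109) and without the arrays numbered 1 (0.0611) or 2 (0.115) and without any 1 of its own arrays (0.0542 to 0.0758).

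p53 targets were higher in UACC-812 (6 of 11, adjusted p = 0.0263, the stress cytokine gene GDF15 by 5.55, MDM2 by 2.45, the cell cycle inhibitor gene CDKN1A by 2.13). They were lower in HCC-1428 (5 of 11, median -0.40, mean -1.37, adjusted p = 0.00715, the death receptor gene TNFRSF10B by -4.93, GDF15 by -3.92, CDKN1A by -2.45). Without _x_at and _s_at probe sets these had adjusted p = 0.125 and 0.163, with the mean of all probe sets 0.0566 and 0.0834, and the UACC-812 call was at 0.0586 without dim genes and 0.0874 without the arrays numbered 3. Tumour suppressors were lower in MDA-MB-231 (3 of 12, with 1 higher, RB1 at 1.02; median -0.11, mean -1.28; adjusted p = 0.0156), where CDH1 was down by -8.66, CDKN2A by -4.31 and its chromosomal neighbour MTAP by -4.08, and in HCC-1395, where the call was lost (adjusted p = 0.0826 with an estimated correlation). The MDA-MB-231 call had adjusted p = 0.83 without _x_at and _s_at probe sets and 0.199 with the mean of all probe sets.

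Anti-apoptotic BCL-2 family genes were higher in ZR751 (adjusted p = 0.0305) and DU-4475 (adjusted p = 0.0434). In ZR751 this rested on BCL2, up by 5.09, with BCL2L2 and MCL1 at 0.88 and 0.49, and the call missed without the arrays numbered 2 (adjusted p = 0.0887) or 3 (0.0941), with the mean of all probe sets (0.114) and without _x_at and _s_at probe sets (0.0713). In DU-4475 it rested on BCL2A1, up by 9.88, and BCL2, up by 4.04, with a median of 0.27 against a mean of 2.20, and the call missed without any 1 of its arrays (adjusted p = 0.087, 0.0724 and 0.0852 without replicates 1, 2 and 3). By cameraPR the BCL-2 effectors and the BH3-only genes were called in 0 lines, each also with 0 lines at an unadjusted p under 0.05. Known regulators of MCL1 (lowest adjusted p = 0.0822) and the caspases and their inhibitors (lowest adjusted p = 0.11) were called in 0 lines, each with 1 line at an unadjusted p under 0.05.

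The main axis among the lines ran from mesenchymal to luminal. The first principal component of the line means held 19.87% of the between-line variance, with a second of 7.91%. HS-578T (score -105.67), BT-549 (-91.21) and HCC-1395 (-81.90) lay at the negative end and HCC-1419 (66.87) at the positive end. The strongest negative loadings were those of CAV1, MSN, VIM, the collagen cross-linking gene LOXL2, TGFBI, P3H2, the caveolar genes CAVIN1 and CAV2, the tropomyosin gene TPM2 and CCN2. The strongest positive ones were TFF1, TFF3, AGR2, TOX3, TTC39A, ALDH3B2, SCGB2A2, PRR15L, ADIRF and the luminal pioneer factor gene FOXA1. All 16 luminal and all 13 junction genes had positive loadings, and 0 of the 18 mesenchymal, 0 of the 15 interferon response and 0 of the 10 MHC class I genes did. The median loading of each list was set against 10000 random lists of the same size and similar mean expression. The luminal, estrogen response, junction and 17q23 lists lay at percentile 100, and the mesenchymal, basal, interferon and MHC class I lists at 0.00. Others also lay near an end, such as the 20q13 list at 99.90, the 1q21 list at 99.70 and proliferation at 0.01. Genes of the random lists were drawn singly, while genes of a fixed list can vary together. Extreme percentiles could arise from that alone, so they are no test of a list. No test was made of the share itself, which was 19.54%, 19.67% and 20.42% within replicates 1, 2 and 3 (29 lines in replicate 3).

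**Figure D5:**
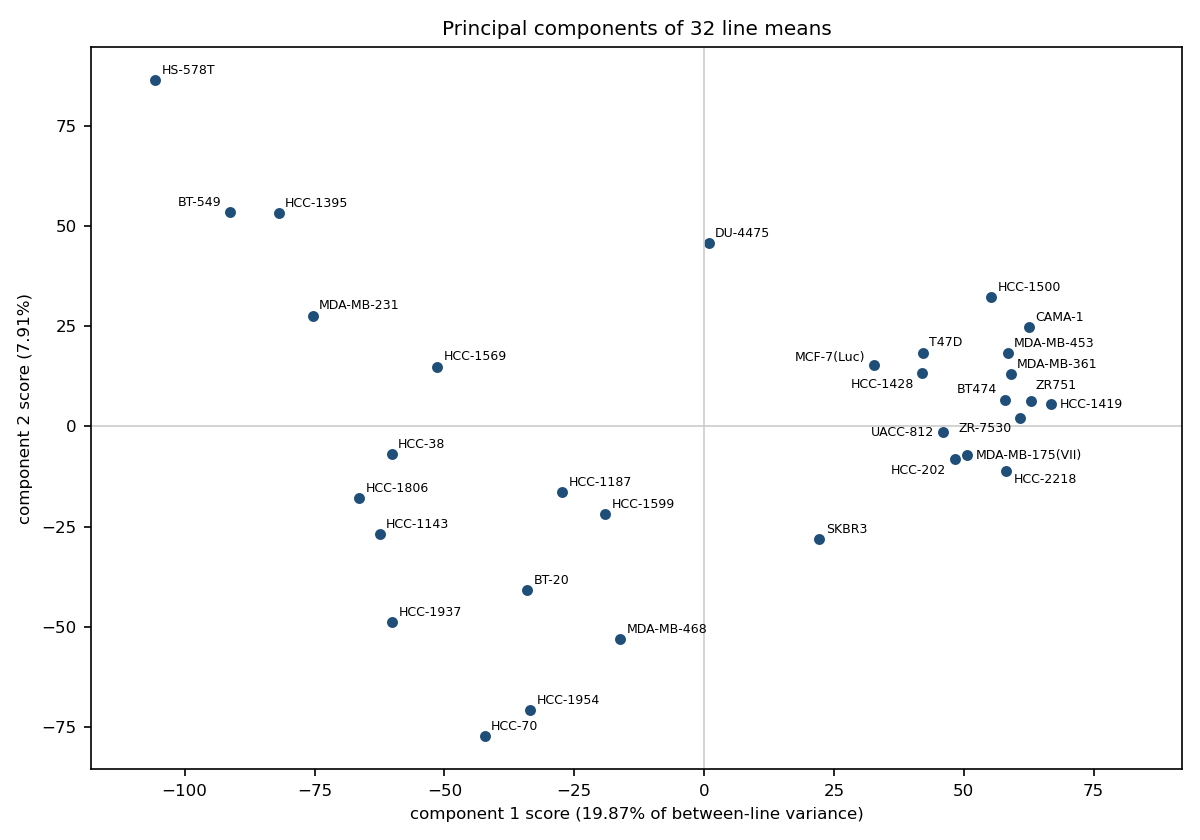
Scores of the 32 line means on the first component (x axis, 19.87% of between-line variance) and the second (y axis, 7.91%), with a point per line. HS-578T lies farthest left (-105.67) and HCC-1419 farthest right (66.87).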

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

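Leaving out HCC-1599 was chosen after seeing the data; all other alternatives were planned. Over all alternatives, 620 counts and main values were recomputed, of which 577 held, 42 moved and 1 turned, and 1577 values of single genes and lists, of which 1512 held, 55 lost the threshold, 9 gained it and 1 turned. A count was taken to hold within a ratio of 1.5 to the main count. Of the 620, 315 came from leaving out arrays, where 313 held. The leading genes of the lines lay far past the threshold, so these totals say little on results near it. Arrays give signal over background, so genes near the lower end of the scale are limited by background, and their folds carry the deposited background step. The fold limit keeps the number of calls close to the number of pairs that differ by 2-fold. Quantile normalization, centring, the intensity trend and line medians moved few single values and turned none. Against the deposited values, the largest shift of a line's median difference was 0.190 log2, in MDA-MB-453 with centring. Leaving out 1 array of a line at a time kept at least 94.0% of the line's calls, and over 93 such refits 39 list calls were lost, 12 gained and 0 turned.

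Without _x_at and _s_at probe sets fewer genes are tested. Genes that spanned at least 4-fold fell to 5394 and the calls summed over lines to 52646. By line, calls were 2138 in HS-578T, 1831 in HCC-70, 1569 in HCC-38, 1785 in HCC-1569, 1681 in HCC-1428, 1663 in BT-20, 1802 in BT-549, 1759 in HCC-1806, 1565 in HCC-1500, 1574 in HCC-1954, 1472 in HCC-1937, 1599 in HCC-1419, 1773 in HCC-1395, 1552 in HCC-2218, 1492 in MDA-MB-361, 2417 in DU-4475, 1446 in MDA-MB-468, 1405 in MCF-7(Luc), 1533 in SKBR3, 1745 in MDA-MB-231, 1440 in T47D, 1598 in HCC-1143, 1568 in MDA-MB-453, 1373 in ZR751, 1775 in CAMA-1, 1347 in UACC-812, 1532 in ZR-7530, 1462 in BT474, 1630 in HCC-1599, 1476 in MDA-MB-175(VII), 1502 in HCC-202 and 2142 in HCC-1187. In the same setting 0 genes followed MCL1 (limma), the slope of DOHH was 0.00 (adjusted p = 1), 1 BCL-2 family member (BAD) correlated with MCL1 and 1 neighbour at 1q21 (GOLPH3L) did. With the MCL1 probe set alone replaced by the brightest one left in this setting, 1 neighbour passed as well (median rho 0.29), so the change of that probe set is enough to give this count. BAD kept its probe set in this setting, so its rho changed only through that of MCL1. Its adjusted p also depends on the family members left, which were fewer.

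With the mean of all probe sets of a gene, 0 genes followed MCL1 and r between MCL1 and BCL2L1 was 0.10. With dim genes left out, 2 genes followed MCL1. Without HCC-1599 0 did. The cause was not tested.

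Leaving out arrays by replicate number, the genes following MCL1 ranged from 0 (without replicate 1) to 3 (without replicate 3), genes called in lines from 81976 to 82388, list calls from 274 to 316 (single arrays left out included), 1q21 neighbours fell from 11 to 10 each time, and r between MCL1 and BCL2L1 ranged from -0.18 to -0.09.

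With the replicate block 81833 calls were made, of which 81711 were shared with the fit without it (99.9% of that fit). Deviations of arrays with the same number in different lines had a mean correlation of -0.000 (lowest -0.314, highest 0.396, 9.6% of pairs over 0.1). On average the numbers thus paired nothing, but batches shared by only some lines could not be seen in that mean. The neural list in UACC-812 (adjusted p = 0.0517) and the ribosomal list in HCC-2218 (0.05) missed the threshold with the replicate block.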

Other observations

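The tests here were chosen after the result was seen, except those of the main axis, of a longer stretch of chromosome 1 and of p53 activity. Runs of 11 neighbouring genes were scanned in each line for a shared difference from the other lines, against 1000 shuffles of gene order. Some gene families and the X chromosome were left out after a first look at the scan, and all regions named were chosen after their values were seen. In MDA-MB-468 a run of S100 genes on chromosome 1, from LORICRIN to S100A2, had a median difference of 4.59 (95th percentile of shuffles 1.49), with LORICRIN and PGLYRP4 at 0.01, S100A12 at -0.00 and S100A5 at -0.01. The same cluster, from PGLYRP4 to S100A14, had a median of -3.59 in HCC-1500, with PGLYRP4 at -0.00, S100A12 at -0.01, S100A5 at 0.01 and S100A3 at -0.58. In UACC-812 the run from MSL1 to KRT24 on chromosome 17 had a median of 4.01 (limit 1.54), with RAPGEFL1 at 7.06 and the retinoic acid receptor gene RARA at 4.68, but TNS4 at 0.72 and CCR7 at 0.05. The cystatin genes CST1 and CST4 on chromosome 20 were raised by 9.25 and 7.03 in MDA-MB-231, in a run with a median of 3.48 that also held PAX1 at -0.01, SSTR4 and CST8 at 0.00, CD93 at -0.02 and NXT1 at 0.47.

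In MDA-MB-468 the run from CORO7 to PPL on chromosome 16 had a median of -4.09 (limit -1.35), with HMOX2 at -6.37, GLYR1 at -5.66 and UBN1 at -5.42, but DNAJA3 at -0.66, CDIP1 at -0.14, CORO7 at -0.04 and DNAAF8 at 0.02. On chromosome 8, the run from PDP1 to MTERF3 had a median of -2.85 in SKBR3 (CDH17 at -0.09), and that from SFRP1 to VDAC3 a median of -2.78 in HCC-70 (ANK1 at -0.18, DKK4 at -0.41, PLAT at -0.83). In HCC-1500 the run from RAX to BCL2 on chromosome 18 had a median of 2.59, with PMAIP1 at 3.47 and BCL2 at 7.09 but RAX at 0.00, MC4R and CDH20 at -0.00, TNFRSF11A at -0.30 and ACTBP9 at -0.61. Altogether 132 regions were higher and 88 lower, and 30 lines had a higher region. Gene order says nothing on copy number, which was not measured here.

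MCL1 was highest in HCC-1599. The other 4 MCL1 probe sets gave a median difference of 1.83, which argues against the signal of a single probe set. The smaller of the differences under other scalings was 2.07, which argues against array scaling. The 1q21 neighbours had a median difference of 0.42 in this line (15 of 20 higher, SD 1.34, from ANXA9 at -3.42 to ANP32E at 2.06), which argues against a gain of the whole neighbourhood by as much as MCL1. No biological explanation besides such a gain was tested.

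For the 1q21 neighbours that track MCL1, 10 passed without HCC-1599 and 13 with the first component taken out, which argues against that line alone and against the main axis among the lines. With the other MCL1 probe sets a median of 8 passed (from 1 to 11), so the part played by the chosen probe set stays open. The 20 measured genes flanking this stretch, from CHD1L to SNX27, had a median rho of 0.42 with MCL1, at percentile 99.9 of other runs. A change of a longer stretch of chromosome 1 could therefore underlie the relation, as a hypothesis found and tested on the same data.

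BAX differed between replicate arrays more than other family members, and its 2 probe sets moved together (r of deviations 0.94). The deviations correlated by 0.08 with those of the ACTB 3' to 5' difference, and the replicate SD stayed at 0.68 after quantile normalization, which argues against RNA quality and array scaling. The other 11 p53 targets had a median r of 0.04 with BAX (GDF15 -0.21 to FAS 0.30), which gives no sign of a shared p53 activity. Deviations of 35 genes correlated with BAX by at least 0.5 in size, against at most 4 in 100 shuffles, EML2 (0.78) and PPP3R1 (0.77) first. The cause stays open, and no biological explanation besides p53 activity was tested.

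The counts were repeated in 100 groupings of the arrays, the real one included. The real one alone gave as many genes that differed between lines (11589, highest other 223) and genes of at least 4-fold (8315, highest other 154). The same held for the calls summed over lines (81805, highest other 2195) and the BCL-2 family members (13, highest other 0). Arrays of one line correlated by at least 0.9943 and arrays of different lines by at most 0.9600, so this outcome was to be foreseen. It shows that replicates resemble each other and excludes nothing further. For the list calls the real grouping gave 299 and the highest other 227. Random groupings can thus pass many pairs of list and line, so the larger total does not exclude chance for single list calls. Why other groupings gave that many was not tested. For each line with 3 arrays the real count was the largest, which was to be foreseen in the same way. It was at least 2123 calls, against at most 1040 in any other grouping. For the genes following MCL1, 4 of the 100 gave 1 or more, with a highest other of 3.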
